A study of Mus musculus with 74 samples.

How the data were processed

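Adipocytes of mice carrying Adiponectin-Cre and the NuTRAP allele, which tags adipocyte nuclei and ribosomes with fluorescent proteins, were profiled in brown adipose tissue (BAT) and inguinal white adipose tissue (WAT). Samples were taken at 6 Zeitgeber times (ZT) 4 h apart, from ZT1 to ZT21. Per the labels' protocols, ribosome-bound RNA was pulled down with anti-GFP antibodies and 250 ng went into directional RNA-seq libraries, nuclei for ATAC-seq were sorted by FACS and made into Omni-ATAC libraries, and BMAL1 ChIP-seq used inguinal WAT of C57BL6J mice at ZT4. The analysis used 35 RNA libraries, 36 ATAC libraries and 2 BMAL1 ChIP libraries. The ChIP input library was not used here. Each depot and time had 3 RNA libraries, except BAT at ZT17, which had 2. The labels give no diet, feeding schedule, sex or age, so no feeding comparison could be made. They also do not say that replicates are separate animals, so all p-values measure only the spread between libraries. Zeitgeber time counts hours from lights on. The light schedule is not given in the sources used here, and ZT13, ZT17 and ZT21 were taken as the dark phase by the usual convention of lights off at ZT12.

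The authors' RNA table holds estimated counts per Ensembl gene, deposited without normalization. The submitters' processing notes name STAR 2.7.5, RSEM 1.3.0, HOMER, DESeq2, limma and the mm10 build without saying which step each served. The table had 55487 genes, of which 55394 were matched to a symbol by their Ensembl identifier, and 1 column that belonged to no listed sample was not used. Whether counting used strand is not given in the sources used here, so counts of overlapping antisense genes and of near-identical copies were taken as uncertain. The authors also deposited TPM per library with JTK_CYCLE results for each depot, and each such table gives a p-value per gene and a q-value, the p-value adjusted over genes. The deposited ATAC tables hold raw tag counts per peak, made with HOMER on one mm10 peak set per depot of 150 bp regions, per the file headers. In the authors' ATAC tables with JTK_CYCLE results, each library's signal is its raw tags divided by one factor, which was checked on the values. The deposited BMAL1 table gives, per the file headers, the HOMER peak score of a peak set pooled over the ChIP libraries and the signal of each as tags scaled to one fixed total per library, on mm10 and with regions of 212 bp. The submitters' processing notes name Bowtie2 2.4.1 for the ChIP samples. The JTK_CYCLE phase in hours and the JTK_CYCLE amplitude score were deposited as well and were not used for any value given here. The version of HOMER and of JTK_CYCLE is not given in the sources used here.

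RNA totals ran from 4980147 to 46274438 counts in BAT and from 1301522 to 6481154 in WAT. ATAC tags in peaks ran from 3959384 to 12811242 in BAT and from 1623006 to 5294923 in WAT. The BMAL1 libraries had 29167659 and 29250608 tags. Expected counts were rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 scaled libraries by TMM, kept genes by filterByExpr, fitted quasi-likelihood models and adjusted p by Benjamini-Hochberg over all genes tested. A call needed an adjusted p under 0.05. Rhythms were fitted in each depot with a cosine and a sine of period 24 h, tested together. The fit gives a time of peak and a peak-to-trough difference. Its standard error (SE) comes from the delta method, scaled to the quasi-likelihood F, and the SE of a log2 difference is its size divided by the square root of F. The dark phase was compared with the light phase by a contrast of the 6 time means. BAT was compared with WAT with time as a factor and a fold of at least 2. A difference of rhythm between depots was tested through the interaction of depot with the cosine and sine, and its size is given as the amplitude of the difference between the fitted curves. ATAC tag counts were fitted with the same rhythm model. The deposited counts allowed the count model named in the design, so no other ATAC test was needed. Levels are CPM scaled by TMM, and the depot comparison was scaled over all RNA libraries together.

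Gene lists were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and again with the correlation estimated in each list, and adjusted over the 31 or 33 lists with enough members. Peaks were assigned to genes as the deposited annotation gives them, within 10 kb of a start site. Overlaps of regions were found with bedtools 2.31.1 and needed at least 75 bp. Odds ratios come from Fisher's exact test, with both tails counted and 95% intervals, and genes or regions are not independent replicates there. Cochran-Mantel-Haenszel odds ratios were taken over 10 bins of mean expression. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

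The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists covered the core clock, thermogenesis, the creatine cycle, the calcium cycle, de novo lipogenesis, triglyceride synthesis, lipolysis, fatty acid uptake, fatty acid oxidation, glucose uptake and glycolysis, insulin and feeding response, NAD metabolism, adipokines, heat shock and cold-inducible genes, glucocorticoid response, the electron transport chain, cholesterol synthesis, immediate early genes, brown identity and white identity. Further lists held markers of adipocytes, macrophages, endothelial cells, fibroblasts or progenitors, mural cells, skeletal muscle, lymphocytes, mammary epithelium, Schwann cells or nerve, mast cells and erythroid cells, and the ribosomal protein and mitochondrially encoded genes. The thermogenesis and creatine cycle lists were chosen knowing that the published study is concerned with them, so they are not independent evidence of direction. Named genes were the 10 with the largest peak-to-trough difference in each depot among calls with a mean of at least 5 CPM and no overlap of replicates between the highest and lowest time, every core clock gene, and up to 4 members of each list with the smallest adjusted p. For the depot comparison they were the 10 largest differences each way at a mean of at least 10 CPM, for the rhythm difference the 10 smallest adjusted p and the list members past the threshold. For regions they were the 5 largest amplitudes or scores and the regions near core clock, thermogenesis and creatine cycle genes. Which of these genes the text names was chosen after their values were seen.

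The models were tested on simulated counts with 200 changed genes or regions of known size. Of the rhythms simulated with a peak-to-trough log2 difference of 2, 89% were recovered in BAT RNA, 44% in WAT RNA, 100% in BAT ATAC and 100% in WAT ATAC. At a peak-to-trough log2 difference of 1, the shares were 52%, 3%, 84% and 87%. For dark against light, a log2 change of 1 was recovered in 74% of genes in BAT and 32% in WAT. The depot comparison recovered 99% at a log2 change of 1.5, and the rhythm difference 48% where the depots differed by a peak-to-trough log2 of 2. False calls were 0.995% to 6.54% of all calls. The counts were simulated independently for each gene, so variation shared by many genes of a library was not simulated, and real false calls may be more frequent.

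Alternatives were the size factors of DESeq2 1.42.0, no expression filter or a mean of at least 5 CPM, DESeq2 or limma-voom in place of edgeR, time as a factor with 6 levels, a minimum fitted fold of 1.5, one fit of all RNA libraries, the replicate number as a block, no fold or a fold of 4 between depots, and leaving out each library in turn. For regions they were start site windows of 1 kb and 50 kb, an overlap of 1 bp, the BMAL1 peaks with the higher scores, strata of expression, BMAL1 peaks set against BAT rhythms, and the deposited JTK_CYCLE calls. After seeing the data, 4 further alternatives were added, which left out libraries with a high share of counts in ribosomal RNA (rRNA) loci or from mitochondrially encoded genes, took the mitochondrial share as a covariate, removed both kinds of genes before normalization, or used the deposited q-value.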

Results

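Adipocytes of brown adipose tissue (BAT) and inguinal white adipose tissue (WAT) of mice were sampled every 4 h around the day, from ZT1 to ZT21. Ribosome-bound RNA was measured in 17 BAT and 18 WAT libraries, with 3 libraries per depot and time except 2 for BAT at ZT17. Chromatin accessibility of sorted adipocyte nuclei was measured by ATAC-seq in 18 libraries of each depot. Binding of BMAL1, the clock transcription factor encoded by Arntl, was measured by ChIP-seq in 2 libraries of inguinal WAT taken at ZT4. RNA libraries held 4980147 to 46274438 counts in BAT and 1301522 to 6481154 in WAT, and ATAC libraries 3959384 to 12811242 and 1623006 to 5294923 tags in peaks. WAT libraries also carried more RNA of mitochondrial and ribosomal origin. Mitochondrially encoded genes took a median of 0.280% of counts in BAT (range 0.126% to 2.25%) and 9.64% in WAT (range 0.686% to 27.6%). Ribosomal RNA loci, taken here as CT010467.1, Gm42418 and Lars2, took 0.813% to 4.64% of counts in BAT and 5.26% to 66.0% in WAT. Grouping these genes as such loci was a choice made here and is not given by the labels. WAT libraries at ZT5 replicate 3, ZT9 replicate 3 and ZT17 replicate 2 had 66.0%, 60.7% and 53.0% of counts in these loci. The median correlation of log2 levels across genes was 0.961 between replicates in BAT and 0.813 in WAT, and genes are not independent there. Libraries of different times gave 0.955 in BAT and 0.799 in WAT.

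**Figure D1:**
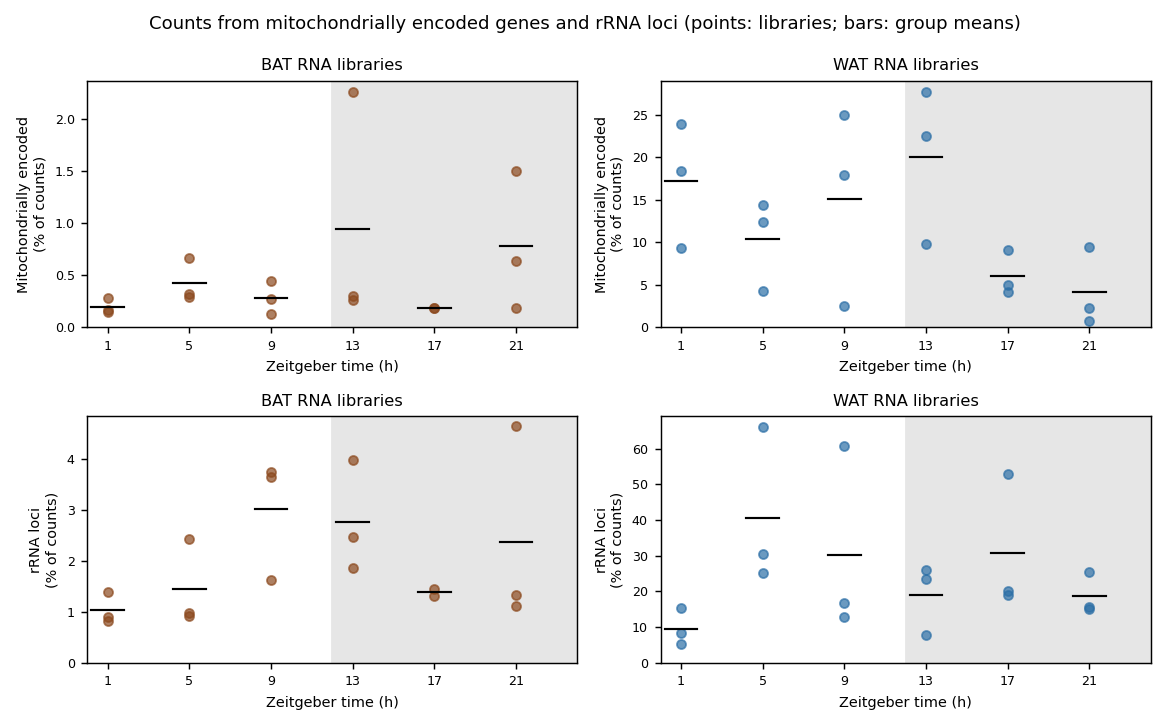
Share of counts (%) from mitochondrially encoded genes and from ribosomal RNA loci against Zeitgeber time (h) in each RNA library, with points for libraries, bars for group means and grey for the dark phase. In WAT the mitochondrial share averaged 17.2% at ZT1 and 4.12% at ZT21, while in BAT no library exceeded 2.25%.

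The depot comparison asked which transcripts separate the pulled-down RNA of BAT from that of WAT. Brown adipocytes make heat with the uncoupling protein Ucp1 (ENSMUSG00000031710), whose level was 1339 CPM ± 616 in BAT and 61.7 CPM ± 45.0 in WAT (SD, n = 17 and 18). Its log2 difference was 4.67 ± 0.31 (SE, edgeR adjusted p = 3.68e-16), and the lowest BAT library, at 666 CPM, exceeded the highest WAT library, at 175 CPM. Cidea (ENSMUSG00000024526), a lipid droplet protein of brown fat, differed by 4.25 ± 0.25 (edgeR adjusted p = 1.15e-17), with 2200 CPM in the lowest BAT library and 481 CPM in the highest WAT library. Cox8b, a subunit of the respiratory chain, differed by 4.33 ± 0.25 (edgeR adjusted p = 7.38e-18). Ckb (ENSMUSG00000001270), the creatine kinase of the creatine cycle that can also make heat, averaged 563 CPM ± 233 in BAT and 121 CPM ± 61.2 in WAT, a log2 difference of 2.27 ± 0.22 (edgeR adjusted p = 8.34e-12). Hoxc9 (ENSMUSG00000036139), a patterning gene of the posterior body, averaged 0.148 CPM in BAT and 248 CPM in WAT, and Hoxc8 averaged 28.6 and 1736 CPM. The lymphocyte genes Bank1, Bcl11b and Rac2 averaged 0.0752, 0.171 and 0.144 CPM in BAT against 66.4, 44.1 and 45.5 CPM in WAT.

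Of 10999 genes tested, 5204 (47.3%) differed between depots by at least 2-fold, 2541 higher in BAT and 2663 higher in WAT. Thermogenesis genes were higher in BAT in 14 of 19 cases and lower in 1, with a median log2 difference of 2.77 (camera adjusted p = 7.79e-05; adjusted p = 0.141 with an estimated correlation). All 14 genes of the electron transport chain were higher in BAT, with a median of 2.78 (camera adjusted p = 8.48e-09; adjusted p = 0.141 with an estimated correlation). Fatty acid oxidation genes were higher in 14 of 18 cases and lower in 1, with Acadvl at 3.48 ± 0.16 and Acaa2 at 3.87 ± 0.19, while the list passed camera at adjusted p = 5.69e-05 (adjusted p = 0.141 with an estimated correlation). Glycolysis genes were higher in 12 of 18 and lower in 1, and Ldhb and Pkm differed by 3.57 and 2.47. Brown identity genes were higher in BAT in 8 of 11 cases and lower in 1, and white identity genes were lower in 7 of 10 and higher in 1. The endocrine factor Nrg4 was higher by 2.08, whereas Lpl, which releases fatty acids from lipoproteins, fell by 1.64 in BAT relative to WAT. Of the creatine cycle list only Ckb, 1 of 4 genes measured, differed, and this list and the thermogenesis list are not independent evidence of direction. Fibroblast markers were lower in BAT in 7 of 7 cases, with a median of -3.69, and macrophage markers in 4 of 5, with a median of -5.69. All 15 mitochondrially encoded genes were lower in BAT, with a median of -5.09. WAT libraries carried more counts of mitochondrial and ribosomal origin. Whether the marker, lymphocyte and mitochondrial genes higher in WAT were expressed by adipocytes or came from background RNA was not tested.

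Rhythm of BAT RNA was tested to find which brown adipocyte transcripts followed a 24 h cycle, with sizes given as fitted peak-to-trough log2 differences ± SE over 17 libraries. Core clock genes passed in a larger share than the genes of any other list. Arntl (ENSMUSG00000055116), whose protein switches on the other clock genes, peaked at ZT0.0548 with a difference of 4.92 ± 0.54 (edgeR adjusted p = 1.31e-04). Its target Dbp (ENSMUSG00000059824) peaked at ZT10.2 with 3.36 ± 0.33 (edgeR adjusted p = 4.15e-05). Clock followed Arntl with 1.27 ± 0.16 at ZT0.177 (edgeR adjusted p = 5.15e-04). The repressors Nr1d1 and Nr1d2 changed by 2.24 ± 0.44 and 2.03 ± 0.21 with peaks at ZT5.26 and ZT9.51, Per1 by 2.17 ± 0.35 at ZT10.9 and Tef by 1.63 ± 0.14 at ZT11.7. Per2 did not pass (edgeR adjusted p = 0.145). Single genes of other lists also cycled, while the insulin and feeding response list passed in 2 of 14 cases (8 adjusted over the list alone). Adrb3 (ENSMUSG00000031489), the noradrenaline receptor that starts lipolysis and heat production, peaked at ZT0.121 with 1.62 ± 0.26 (edgeR adjusted p = 0.00312). Angptl4, an inhibitor of Lpl induced by fasting, peaked at ZT2.79 with 2.14 ± 0.26 (edgeR adjusted p = 3.45e-04), and Irs1, an insulin signalling adaptor, at ZT23.5 with 1.97 ± 0.30. Angptl8, which is induced by feeding, peaked at ZT20.5 with 2.76 ± 0.42 (edgeR adjusted p = 0.00242).

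**Figure D2:**
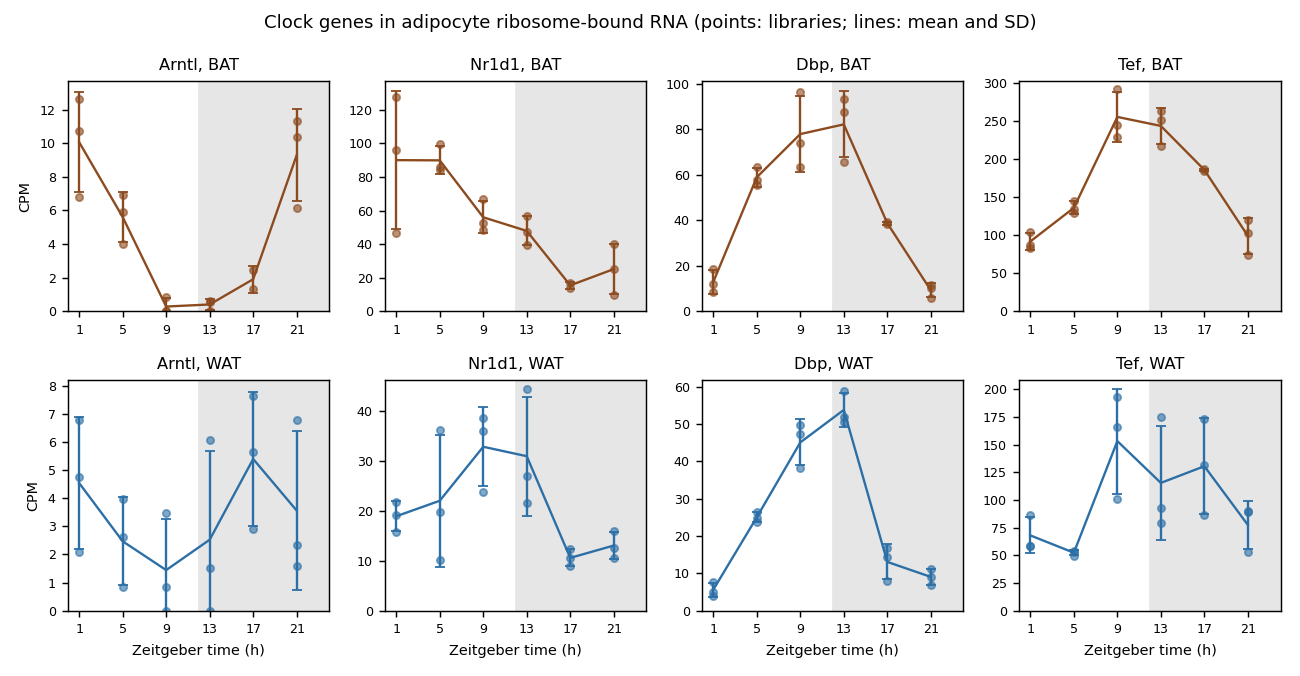
Level (CPM) of Arntl, Nr1d1, Dbp and Tef against Zeitgeber time (h) in BAT and WAT RNA, with points for libraries, lines and bars for mean and SD, and grey for the dark phase. In BAT, Arntl averaged 10.1 CPM ± 2.98 at ZT1 and 0.286 CPM at ZT9, and in WAT Dbp averaged 5.61 CPM at ZT1 and 53.8 CPM ± 4.53 at ZT13.

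In total 1136 of 12394 genes (9.17%) were rhythmic in BAT, with a median peak-to-trough fold of 1.93. The fitted peaks were most frequent around ZT1 (31.5%) and ZT13 (29.0%). Of the core clock, 15 of 18 genes passed over all genes and 15 adjusted over the list alone. Glucocorticoid response genes passed in 7 of 10 cases (7 adjusted over the list alone), including the metallothionein Mt2 with 1.77 at ZT10.4 and Fkbp5 with 2.10 at ZT13.5. Lipolysis genes passed in 6 of 12 cases (8 adjusted over the list alone), fatty acid oxidation in 5 of 18 (7) and glycolysis in 4 of 18 (5), led by Pfkfb3 with 1.75 ± 0.25 at ZT23.7. De novo lipogenesis passed in 5 of 15 cases (8 adjusted over the list alone), with Thrsp at 0.87 and ZT17.8, and triglyceride synthesis in 1 of 10 (4). Thermogenesis passed in 5 of 19 (5 adjusted over the list alone), among them Adrb3, while none of the 5 creatine cycle genes passed, and Ckb had an edgeR adjusted p = 0.130. The latter lists are not independent evidence of direction. Heat shock genes passed in 4 of 14 cases and 11 adjusted over the list alone. None of the macrophage, endothelial or fibroblast markers passed. The number of rhythmic genes rested on single libraries and ranged from 460 to 3379 when each was left out. The genes given here with an SE passed without any one library and in every setting in which single genes were scored. Time as a factor, which gives no fitted amplitude, was not scored for single genes of the rhythm tests.

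Rhythm of WAT RNA was tested to find which white adipocyte transcripts followed a 24 h cycle, and among those that passed were genes of fat synthesis with peaks in the dark phase. Sizes are again fitted peak-to-trough log2 differences ± SE, over 18 libraries. Thrsp (ENSMUSG00000035686), a lipogenic nuclear protein driven by insulin and carbohydrate, changed by 2.97 ± 0.40 with a peak at ZT18.6 (edgeR adjusted p = 6.71e-04). Me1, which makes NADPH for fatty acid synthesis, changed by 2.95 ± 0.42 at ZT20.5 (edgeR adjusted p = 8.63e-04). Elovl6 changed by 2.57 ± 0.41 at ZT21.2, and Srebf1, the lipogenic transcription factor, by 2.20 ± 0.39 at ZT20.5 (edgeR adjusted p = 0.00245 and 0.00506). In triglyceride synthesis, Gpam changed by 2.67 ± 0.44 at ZT21.2 and Dgat1 by 2.13 ± 0.39 at ZT21.1. The lipase inhibitor G0s2 peaked at ZT17.9 with 3.13 ± 0.46 (edgeR adjusted p = 0.00130), and the feeding-induced Angptl8 at ZT18.9 with 5.21 ± 0.70 (edgeR adjusted p = 6.71e-04). The adipokine Retn peaked at ZT20.3 with 2.28 ± 0.44, and the sterol gene Hmgcs1 at ZT20.2 with 1.89 ± 0.29. Among clock genes, Dbp changed by 3.24 ± 0.33 at ZT10.6 (edgeR adjusted p = 2.75e-05). Arntl, Per1 and Clock did not pass (edgeR adjusted p = 0.439, 0.351 and 0.698). Ckb peaked at ZT19.4 with 1.37 ± 0.34 (edgeR adjusted p = 0.0292), a call lost in 7 of 18 fits that left out 1 library.

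**Figure D3:**
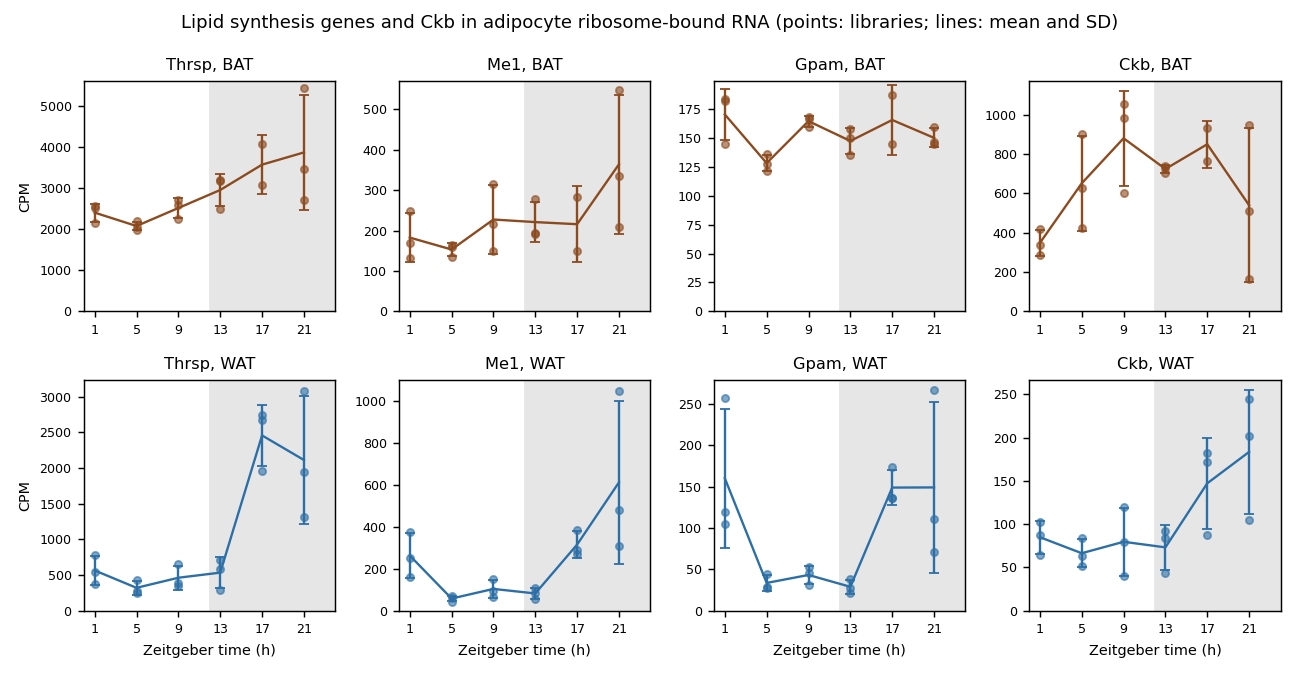
Level (CPM) of Thrsp, Me1, Gpam and Ckb against Zeitgeber time (h) in BAT and WAT RNA, with points for libraries, lines and bars for mean and SD, and grey for the dark phase. In WAT, Thrsp averaged 319.6 CPM ± 98.5 at ZT5 and 2455 CPM ± 432 at ZT17, and Ckb 66.4 CPM ± 16.4 at ZT5 and 183.5 CPM ± 72.0 at ZT21.

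In total 1257 of 12703 genes (9.90%) were rhythmic in WAT, with a median peak-to-trough fold of 3.24, and 47.3% of the peaks fell around ZT21. The count ranged from 474 to 2545 when each library was left out. De novo lipogenesis genes passed in 8 of 15 cases (10 adjusted over the list alone) and triglyceride synthesis in 7 of 10 (9), all of them with peaks in the dark phase. Cholesterol synthesis passed in 4 of 12 cases (4 adjusted over the list alone), adipokines in 4 of 11 (4) and white identity in 3 of 10 (5). The core clock passed in 5 of 18 cases (6 adjusted over the list alone), of which Nr1d1, Nr1d2, Tef and Bhlhe40 were lost in 5, 11, 13 and 10 of 18 fits without 1 library. Thermogenesis passed in 1 of 18 cases, Kcnk3, with 1.74 ± 0.37 at ZT18.7, and the creatine cycle in 1 of 5, Ckb (1 and 2 adjusted over the list alone). Cytosolic ribosomal protein genes passed in 23 of 87 cases (39 adjusted over the list alone), 21 with a peak in the dark phase. The muscle genes Trdn and Ryr1 peaked in the light phase, with 5.13 ± 0.78 at ZT6.78 and 4.48 ± 0.77 at ZT7.47, while the skeletal muscle list, which holds neither, passed in 1 of 10 cases. The mean mitochondrial share of counts also varied between times, with 17.2% ± 7.35 at ZT1, 10.3% ± 5.33 at ZT5 and 15.1% ± 11.5 at ZT9. It was 20% ± 9.15 at ZT13, 6.06% ± 2.68 at ZT17 and 4.12% ± 4.66 at ZT21 (SD, n = 3 each). None of the 15 mitochondrially encoded genes was called rhythmic, so a daily rhythm of this share was not shown. On simulated counts, 44% of WAT rhythms with a peak-to-trough log2 difference of 2 were found, against 89% in BAT.

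Whether rhythms differed between depots was tested through the interaction of depot and rhythm, with sizes given as the amplitude of the difference between the fitted log2 curves. The test took one spread for both depots, although WAT replicates correlated less (median 0.813 against 0.961 in BAT). The lipogenic gene Elovl6 differed by 1.48 ± 0.23 and the sterol gene Fdft1, which peaked at ZT12.6 in BAT and ZT19.4 in WAT, by 1.36 ± 0.21 (edgeR adjusted p = 0.00381 for both). Gpam differed by 1.23 and was flat in BAT, with a peak-to-trough difference of 0.12 (edgeR adjusted p = 0.798). Pcx differed by 0.77, Lpin1 by 0.85 and Acacb by 0.88, and Thrsp by 0.99 (edgeR adjusted p = 0.0153). The potassium channel Kcnk3, counted with thermogenesis genes, peaked at ZT10.6 in BAT and ZT18.7 in WAT and differed by 1.21 ± 0.24 (edgeR adjusted p = 0.00823). Arntl was the only one of 17 core clock genes called, with a difference of 2.12 ± 0.53 (edgeR adjusted p = 0.0230), and that call was lost in 2 of 7 other settings. Nr1d1, Clock and Per3 fell short of the threshold (edgeR adjusted p = 0.0563, 0.0804 and 0.0946), so a missing call does not show equal rhythms. Adrb3 differed by 0.73 (edgeR adjusted p = 0.0471), lost in 24 of 35 fits without 1 library, and Ckb by 0.94 (edgeR adjusted p = 0.0340), lost in 9 of 35.

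The rhythm of 1418 of 10999 genes (12.9%) differed between the depots, with a range of 569 to 3019 when each library was left out. They included 6 of 10 triglyceride synthesis genes (6 adjusted over the list alone), 5 of 15 lipogenesis genes (7), 5 of 18 fatty acid oxidation genes (10), 3 of 12 lipolysis genes (5), 4 of 18 glycolysis genes (5), 2 of 19 thermogenesis genes (1) and 29 of 87 ribosomal protein genes (51). Among 11065 genes tested in both depots, 1058 were rhythmic in BAT, 1156 in WAT and 137 in both, where 110.5 would be shared by chance (odds ratio 1.31, 95% interval 1.08 to 1.59, Fisher's exact p = 0.00695). Of the 137 genes, 72 peaked within 4 h in the depots and 19 more than 8 h apart.

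Dark and light phases of BAT were compared to find transcripts whose mean level followed the time when mice usually eat and move. Nr1d1, a repressor that links the clock to metabolism, was lower in the dark, with a log2 difference of -1.54 ± 0.24 (edgeR adjusted p = 0.00584). The lipase inhibitor G0s2 rose by 1.17 ± 0.19 in the dark (edgeR adjusted p = 0.00584), and the fasting-induced Angptl4 fell by 1.26 ± 0.18 (edgeR adjusted p = 0.00541). Acot11, which hydrolyses acyl-CoA, rose by 0.94 ± 0.12 (edgeR adjusted p = 0.00132), although this call was lost in 1 of 10 other settings. The sizes come from 9 light and 8 dark libraries. Of 12394 genes, 161 (1.3%) differed, 106 higher and 55 lower in the dark, with a range of 56 to 194 when each library was left out. Another split of the same libraries called 344 genes. Cytosolic ribosomal protein genes rose in 19 of 88 cases (47 adjusted over the list alone) with a median of 0.29, and the list passed camera at adjusted p = 1.87e-24 (adjusted p = 0.380 with an estimated correlation). None of the 15 mitochondrially encoded genes passed, with a median of 0.83 and camera adjusted p = 0.0376 (adjusted p = 0.827 with an estimated correlation). They took 0.301% ± 0.170 of counts in the light and 0.688% ± 0.776 in the dark (SD, 9 and 8 libraries). Of the core clock, 4 of 18 genes differed (5 adjusted over the list alone). Lipogenesis differed in 1 of 15 cases (5 adjusted over the list alone) and insulin response in 2 of 14 (5). Of the thermogenesis list 1 of 19 genes rose, while none of the 5 creatine cycle genes differed. The erythroid markers passed in 0 of 5 cases and 5 adjusted over the list alone, with a median of 0.83.

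The same comparison in WAT found higher levels in the dark for some genes of lipid synthesis, the pathway that stores carbon as fat. Thrsp rose by 1.69 ± 0.25 and G0s2 by 1.82 ± 0.27 (edgeR adjusted p = 0.00138 for both), from 9 light and 9 dark libraries. Angptl8 rose by 3.07 ± 0.53 (edgeR adjusted p = 0.00362) and Pcx, which supplies oxaloacetate for fatty acid synthesis, by 0.94 ± 0.17 (edgeR adjusted p = 0.00548). Acacb rose by 1.20 ± 0.23, Slc25a1, the citrate carrier, by 0.93 ± 0.19, Me1 by 1.11 ± 0.25, Gpd1 by 1.08 ± 0.23 and Agpat2 by 1.04 ± 0.23. These 9 genes passed without any one library and in every setting in which they were scored, 9 settings for Angptl8 and 10 for the others. Ppargc1b, an activator of mitochondrial genes, rose by 1.29 ± 0.30 (edgeR adjusted p = 0.0154), lost in 1 of 18 fits without 1 library.

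Of 12703 genes, 953 (7.50%) differed in WAT, 551 higher and 402 lower in the dark. This balance depended on the processing, with 481 higher and 482 lower under DESeq2 size factors, 745 and 830 with DESeq2, 1280 and 1574 without the 3 libraries rich in rRNA, and 210 and 94 with the mitochondrial share as a covariate. The total ranged from 182 to 2011 when each library was left out. The median log2 difference of all genes was -0.10. De novo lipogenesis rose in 5 of 15 cases (9 adjusted over the list alone), with a median of 0.64 and camera adjusted p = 6.06e-06 (adjusted p = 0.158 with an estimated correlation). Triglyceride synthesis rose in 4 of 10 cases (6 adjusted over the list alone), with a median of 0.70 and camera adjusted p = 1.30e-05 (adjusted p = 0.158 with an estimated correlation). Thermogenesis genes rose in 2 of 18 cases (5 adjusted over the list alone), with camera adjusted p = 0.00330 (adjusted p = 0.354 with an estimated correlation), and no creatine cycle gene differed (1 adjusted over the list alone). Cytosolic ribosomal protein genes rose in 21 of 87 cases and fell in 2 (36 adjusted over the list alone), with camera adjusted p = 1.89e-04 (adjusted p = 0.354 with an estimated correlation). Among markers of other cells, macrophage and endothelial markers passed in 0 of 7 cases each (3 each adjusted over the list alone) and muscle markers fell in 2 of 10 (2). These lists passed camera as lower in the dark at adjusted p = 0.0494, 0.0158 and 0.00330 (adjusted p = 0.467, 0.354 and 0.354 with an estimated correlation). Fibroblast markers fell in 5 of 9 cases (6 adjusted over the list alone), with a median of -0.90 and camera adjusted p = 1.19e-04 (adjusted p = 0.339 with an estimated correlation). Their summed level was 694 CPM ± 435 in the light and 318 CPM ± 181 in the dark (SD, 9 libraries each). Muscle markers summed to 174 CPM ± 90.2 and 67.3 CPM ± 62.0, and macrophage markers to 246 CPM ± 131 and 139.9 CPM ± 111. Adipocyte markers, set beside them, summed to 27920 CPM ± 25000 in the light and 39310 CPM ± 22760 in the dark. They rose in 1 of 7 cases (3 adjusted over the list alone), with camera adjusted p = 0.00907 (adjusted p = 0.365 with an estimated correlation).

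Accessibility of regulatory DNA was tested for rhythm to find regions that open and close over the day in adipocyte nuclei. In BAT, a region in the 5' UTR of Adrb3 on chromosome 8 of mm10 (27228513 to 27228663) changed by a fold of 2.53 with a peak at ZT23.8 (edgeR adjusted p = 5.75e-04). An intergenic region beside Npas2, whose protein can pair with BMAL1, on chromosome 1 (39192795 to 39192945) peaked at ZT0.11 in BAT with a fold of 2.55 (edgeR adjusted p = 4.18e-05), and in WAT (39192858 to 39193008) at ZT21.1 with 2.90 (edgeR adjusted p = 1.28e-04). Beside Nr1d1, the intergenic region on chromosome 11 from 98783480 to 98783630 peaked in BAT at ZT6.13 with 1.80 (edgeR adjusted p = 4.32e-04). The only rhythmic region at a creatine cycle gene in WAT lay at the transcription end of Ckb on chromosome 12 (111669048 to 111669198), with a fold of 1.38 at ZT11.0 (edgeR adjusted p = 0.0234). The largest amplitude among the BAT regions named was in an intergenic region at -151516 bp from the start site of Npy, on chromosome 6 (49671119 to 49671269), with a fold of 8.65 at ZT14.4 (edgeR adjusted p = 4.87e-07).

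Of 42572 BAT regions 8053 (18.9%) were rhythmic, and of 25050 WAT regions 3968 (15.8%), over 18 libraries each. Their peaks were most frequent around ZT21, with 24.1% in BAT and 29.8% in WAT. Near core clock genes, 18 of 49 BAT regions at 11 genes and 11 of 45 WAT regions at 8 genes were rhythmic, and 17 of the 18 in BAT and 5 of the 11 in WAT peaked in the light phase. The regions called were not the same in both depots, and those at Arntl and Nfil3, with dark peaks, were called only in WAT. The Npas2 region counts as light in BAT and dark in WAT, on either side of lights on. The Ciart region peaked at ZT10.6 in BAT and ZT11.0 in WAT. Lipogenesis genes had 10 rhythmic regions of 33 in WAT, 9 with a peak in the dark, and triglyceride synthesis genes 8 of 24, 7 in the dark. In BAT these lists had 6 of 46 and 4 of 32, all in the dark. Thermogenesis genes had 8 rhythmic regions of 52 in BAT, at 5 genes, 7 in the dark, and 5 of 17 in WAT, at 4 genes, 2 in the dark. Several of these were at Adrb3, with peaks from ZT21.6 to ZT23.8 in BAT and at ZT1.22 and ZT1.72 in WAT. They lay on either side of lights on, so the counts do not show opposite phases. Regions in BAT and WAT peaked at ZT10.7 and ZT11.0 for Ppargc1a, and at ZT18.7 and ZT18.0 for Cidea. Of 21636 regions present in both depots, 1269 were rhythmic in both (odds ratio 4.65, 95% interval 4.27 to 5.05, Fisher's exact p = 5.03e-265). Their peaks lay within 4 h of each other in 1202 cases (94.7%). Genes with rhythmic RNA more often had a rhythmic region within 10 kb, with an odds ratio of 1.68 in BAT (95% interval 1.44 to 1.95, Fisher's exact p = 1.92e-11) and 1.40 in WAT (1.14 to 1.71, Fisher's exact p = 0.00115). Within bins of expression the BAT value was 1.61 (95% interval 1.38 to 1.86) and the WAT value 1.18, whose interval of 0.954 to 1.45 includes 1. Where both were rhythmic, the region and the RNA peaked within 4 h in 242 of 397 pairs in BAT (60.96%) and 84 of 166 in WAT (50.6%).

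**Figure D4:**
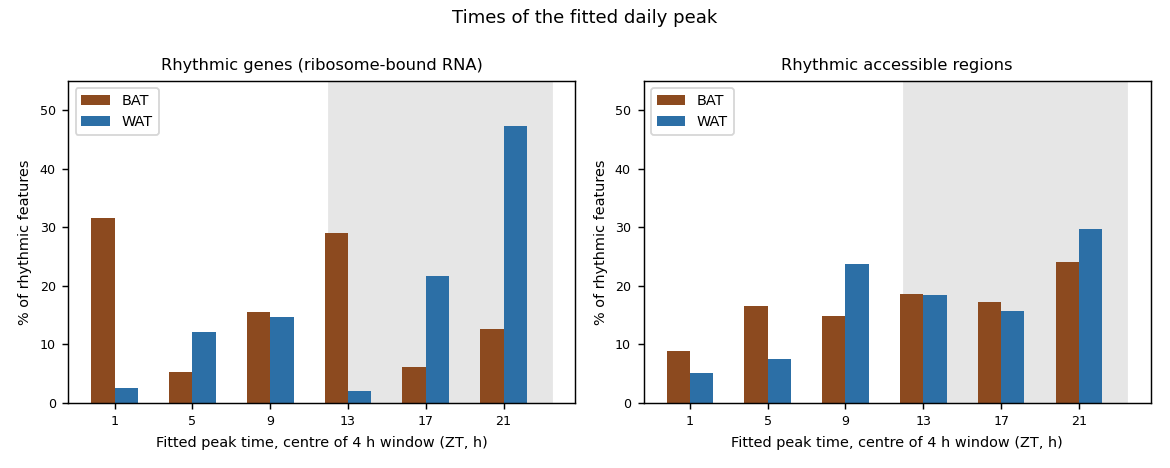
Share (%) of rhythmic genes and of rhythmic accessible regions whose fitted peak fell in each 4 h window of Zeitgeber time (h), with bars for BAT and WAT and grey for the dark phase. RNA peaks gathered around ZT1 (31.5%) and ZT13 (29.0%) in BAT and around ZT21 in WAT (47.3%), whereas accessibility was most frequent around ZT21 in both depots.

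BMAL1 binding in inguinal WAT was mapped to find which genes the clock factor occupies at ZT4, in 2 libraries. Their signals correlated across peaks, which are not independent replicates, at 0.673 on the log2 scale (Pearson) and 0.558 by rank (Spearman). The highest score, 201, belonged to an intergenic peak beside Nr1d1 on chromosome 11 (98783388 to 98783600), with a signal of 195.7 ± 2.75 (SD, n = 2). Tef, Nr1d2 and Per1 followed with scores of 142.6, 139 and 130.6. Of 10368 peaks, 7117 lay within 10 kb of a start site, at 6654 genes. BMAL1 peaks were beside 18 of 19 core clock genes, 12 of 15 lipogenesis genes, 6 of 10 triglyceride synthesis genes, 14 of 20 glycolysis genes, 3 of 22 thermogenesis genes and 2 of 8 creatine cycle genes. Of all 12017 genes tested in WAT with an annotated start site, 5713 had such a peak. Genes with a peak had a higher median level (12.6 CPM against 7.24 without), and the list counts were not tested against the share of all genes. The thermogenesis genes were Esrra, Ppargc1b and Letmd1, with scores of 14.2, 9.59 and 9.07, and the creatine genes Alpl and Ckmt1, with 5.48 and 5.31. No peak was assigned to a fibroblast marker (0 of 9). Rhythmic WAT genes had a peak more often than other genes, with an odds ratio of 1.25 (95% interval 1.11 to 1.42, Fisher's exact p = 2.24e-04). Within bins of expression it was 0.842 (95% interval 0.739 to 0.958, Cochran-Mantel-Haenszel), the opposite direction. Among rhythmic WAT genes, 135 of 631 with a peak (21.4%) and 208 of 568 without (36.6%) had their RNA peak in the light (Fisher's exact p = 7.30e-09). This contrast was not taken within bins of expression.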

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

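The score of lipogenic against adipocyte genes, the test for exchanged ATAC columns and the counts of other splits were chosen only after the results they bear on were seen. The genes below stood out because their 24 h rhythm differed between BAT and WAT in a test of the difference itself. The mitochondrial share of counts, whose mean varied between time points in WAT, was not a covariate in that test. As a covariate it lowered the WAT rhythm calls from 1257 to 615. Whether background RNA in WAT contributes to the differences of rhythm was not tested. The sizes are amplitudes of the difference between the fitted log2 curves. In all, 1418 genes passed. Of 100 splits of the libraries only the real one gave as many, and the highest count among the others was 605. Without 1 library the real count ranged from 569, below that highest other split, to 3019. Without the 3 WAT libraries rich in rRNA it was 3632. Among fat synthesis genes the sizes were 1.48 for Elovl6, 1.23 for Gpam, 1.10 for Me1, 1.02 for Srebf1, 0.99 for Thrsp, 0.88 for Acacb, 0.85 for Lpin1 and 0.77 for Pcx. In fatty acid handling and lipolysis they were 2.12 for Ehhadh, 1.26 for Fabp4, 1.09 for Ppara and 1.08 for Pnpla2. Fabp4 and Ppara were called rhythmic in neither depot alone (edgeR adjusted p = 0.0738 and 0.529 in BAT, 0.0602 and 0.0893 in WAT). Angptl8, a hormone induced by feeding, had 1.46, and the sterol gene Fdft1 had 1.36. In glucose use, Tkt of the pentose phosphate pathway had 1.67 and Ldha had 0.76. Among thermogenesis and creatine cycle genes, Kcnk3 had 1.21, Ckb 0.94 and Adrb3 0.73, and the respiratory chain subunit Cox5a had 0.96. The metallothioneins Mt1 and Mt2 had 1.00 and 1.22, and Arntl was the only core clock gene, with 2.12. The calls of Adrb3, Cox5a, Ckb, Ppara, Srebf1, Fabp4, Me1 and Mt1 were lost in 24, 19, 9, 8, 7, 7, 2 and 1 of 35 fits without 1 library.

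A first pattern set beside these genes is that rhythmic accessibility was shared between depots more than rhythmic RNA. Exchange of BAT accessibility columns by 12 h would leave the rhythm calls unchanged, so it bears only on times of peak and not on how many regions are shared. Such an exchange is argued against, since 0.158% of the regions rhythmic in both depots had peaks more than 8 h apart. Noise in WAT RNA that hides rhythms shared with BAT could account for part of it: 34.1% of the 921 genes rhythmic only in BAT had a WAT peak within 4 h, against 30.6% on average and 33.0% at the 95th percentile of 10000 random pairings. The excess is small, genes are not independent, and the 1019 genes rhythmic only in WAT showed no such excess, with 23.2% against 22.8% on average. For the 1418 genes of the depot by rhythm test the depots differed beyond the spread between libraries, estimated as one spread over both depots. WAT replicates varied more, with a median correlation of 0.813 against 0.961 in BAT. In one fit of all RNA libraries, WAT rhythm calls rose from 1257 to 3555 and BAT calls fell from 1136 to 120. Some of the 1418 calls could therefore come from the larger spread in WAT, and a biological source of the difference stays open.

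The other pattern is that WAT RNA differed between the dark and light phases. Of 100 splits, the real one gave 953 genes and the others 1 at most. RNA from other cells is a candidate source of the genes higher in the light, 35.3% of which (142 of 402) had an accessible start site in sorted adipocyte nuclei, against 76.0% of genes higher in the dark and 65.3% of the others (odds ratio 0.226 within bins of expression, 95% interval 0.181 to 0.281). Whether dilution of adipocyte RNA also accounts for the lipid synthesis genes cannot be told apart: they rose by 0.25 more than adipocyte markers on the log2 scale, with 9 libraries per phase (exact permutation p = 0.170, both tails counted). Adipocyte nuclei did change over the day, with 3968 rhythmic regions and dark peaks in 9 of 10 of those at lipogenesis genes and 7 of 8 at triglyceride synthesis genes, against 58.6% of all. Whether they changed with the RNA of the genes that differed cannot be told apart from background RNA alone, because the regions were few (95 beside genes higher in the dark and 29 beside genes higher in the light) and the odds ratio of a dark peak beside the former was 2.01 (95% interval 0.789 to 5.13), so a change of adipocyte transcription with the time of day stays open too.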

How the results depend on the processing

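The tests without libraries rich in rRNA or mitochondrial counts, with the mitochondrial share as a covariate, without both kinds of genes, and with the deposited q-value were chosen after seeing the data. No named gene reversed under any alternative in which it was scored. Single genes of the rhythm tests were not scored with time as a factor, and a gene without a result in a setting was not scored there. Named genes past the threshold that stayed past it in every setting scored and without any one library were 18 of 42 for BAT rhythm, 27 of 36 for WAT rhythm, 3 of 13 and 9 of 21 for dark against light in BAT and WAT, 24 of 28 between depots and 13 of 23 for the rhythm difference.

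In the order BAT rhythm, WAT rhythm, dark against light in BAT and in WAT, and rhythm difference, the counts of 1136, 1257, 161, 953 and 1418 became 1754, 3046, 471, 1457 and 2156 without a filter and 2465, 2106, 353, 1575 and 2690 with DESeq2. One fit of all RNA libraries gave 120, 3555, 12 and 2599 for the first 4. Time as a factor gave 617 for BAT rhythm, 818 for the rhythm difference and 14063 for BAT ATAC, and limma-voom 2128 for the rhythm difference. The depot count of 5204 became 11706 without a filter, 8272 with no fold and 2140 with a fold of 4. In the authors' deposited tables, 3936 BAT and 2170 WAT genes had a JTK_CYCLE p under 0.05, and the q-value gave 609 and 17 genes and 3873 and 2153 regions. Without the 3 WAT libraries rich in rRNA, WAT rhythm rose to 2675, dark against light to 2854 and the rhythm difference to 3632, and without the 2 BAT libraries rich in mitochondrial counts BAT rhythm fell to 456. With the mitochondrial covariate, WAT rhythm gave 615 and dark against light 304 in WAT and 91 in BAT. The BMAL1 odds ratio of 1.25 was 0.842 within bins of expression and 0.995 against BAT rhythms, and the odds ratio of rhythmic regions at rhythmic WAT genes was 1.18 within bins. Apart from expression at genes with a BMAL1 peak, given below, the causes of these shifts were not tested.

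Replicate numbers showed no detectable pairing of the depots: the median correlation of 17 BAT and WAT libraries of the same number and time was 0.0173. With 2 or 3 libraries per group, this cannot show that the libraries of one number came from different animals. With the number as a replicate block, the counts were 812, 1348, 123, 1282, 5278 and 988 in RNA, in the order BAT rhythm, WAT rhythm, dark against light in BAT and WAT, depots and rhythm difference, and 7412 and 3953 in BAT and WAT ATAC.

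Leaving out 1 library gave 5138 to 5251 genes between depots, 6105 to 8236 BAT regions and 3240 to 4068 WAT regions. BAT rhythm ranged from 460 to 3379: 460 and 494 without ZT1 replicates 2 and 3, 610 and 684 without ZT9 replicates 2 and 3, 699 and 501 without ZT13 replicates 2 and 3, and 609, 3379 and 725 without ZT21 replicates 1, 2 and 3. WAT rhythm ranged from 474 to 2545: 774 and 682 without ZT5 replicates 1 and 2, 613 and 2545 without ZT9 replicates 2 and 3, 606 and 601 without ZT17 replicates 1 and 3, and 593 and 474 without ZT21 replicates 1 and 3. Dark against light in BAT ranged from 56 to 194: 105 and 87 without ZT1 replicates 2 and 3, 86 and 102 without ZT5 replicates 1 and 2, 100 and 106 without replicate 1 of ZT9 and of ZT13, and 84 and 56 without ZT17 replicates 1 and 2, where the lone library is assumed to vary like the others. In WAT it ranged from 182 to 2011: 476 and 182 without ZT1 replicates 1 and 3, 402 and 291 without ZT5 replicates 1 and 2, 312, 298 and 2011 without ZT9 replicates 1, 2 and 3, 319 without ZT13 replicate 3, 387, 1662 and 266 without ZT17 replicates 1, 2 and 3, and 327, 1550 and 407 without ZT21 replicates 1, 2 and 3. The rhythm difference ranged from 569 to 3019: 686 and 569 without BAT ZT9 replicates 2 and 3, 793, 2145 and 676 without BAT ZT21 replicates 1, 2 and 3, 913 and 3019 without WAT ZT9 replicates 2 and 3, and 850 and 636 without WAT ZT21 replicates 1 and 3.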

Other observations

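The counts of other splits, the comparison of expression at BMAL1 targets and the tests of distal regions were chosen only after the results they bear on were seen. Heat shock and glucocorticoid genes link the day to body temperature and hormones. In BAT, Hspb1 peaked at ZT6.16 with a peak-to-trough log2 difference of 1.70 (edgeR adjusted p = 0.00831, lost in 1 of 11 settings), and Fkbp5 at ZT13.5 with 2.10. In WAT, Fkbp5 peaked at ZT10.9 with 1.88 (edgeR adjusted p = 0.0140) and the chaperone Hspa5 changed by 1.62. Prostaglandin synthase Ptges changed by 4.03 in WAT with a peak at ZT20.1 (edgeR adjusted p = 6.71e-04).

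Rhythmic genes in BAT and WAT numbered 1 of 11 and 2 of 12 for NAD metabolism, 1 of 6 and 1 of 6 for the calcium cycle, 1 of 8 and 0 of 8 for immediate early genes, 2 of 10 and 1 of 10 for fatty acid uptake, and 5 of 14 and 1 of 14 for the electron transport chain. Insulin response gave 2 of 14 and 1 of 14, brown identity 2 of 11 and 1 of 9, and adipocyte markers 3 of 7 and 1 of 7 (5 and 4 adjusted over the list alone). In WAT, rhythms were found in 1 of 5 lymphocyte, 1 of 10 muscle, 1 of 6 mural and 2 of 5 Schwann cell markers (4, 1, 2 and 3 adjusted over the list alone). Fibroblast markers passed in 0 of 9 cases there (2 adjusted over the list alone). Between the light and dark phases of WAT, 0 of 7 macrophage, 0 of 7 endothelial, 1 of 6 mural, 1 of 5 lymphocyte and 1 of 4 mast cell markers passed, all with negative medians. Adjusted over the list alone these counts were 3, 3, 3, 4 and 4, and the lists passed camera at adjusted p = 0.0494, 0.0158, 0.0420, 0.00427 and 0.00907 (adjusted p = 0.467, 0.354, 0.354, 0.351 and 0.223 with an estimated correlation). The 5 erythroid markers, the 1 mammary marker measured and the 15 mitochondrially encoded genes gave no call. The mitochondrially encoded genes took 14.2% ± 7.93 of WAT counts in the light and 10.1% ± 9.19 in the dark (SD, 9 libraries each).

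For the other counts, the highest among the other splits was 39 against 1136 for BAT rhythm. It was 772 against 1257 for WAT rhythm, a count that fell as low as 474 without 1 library. Between depots it was 1814 against 5204, with 24 against 8053 for BAT regions and 237 against 3968 for WAT regions. In this order, 1 of 100 splits, the real one, reached each count, and 2 of 100 for dark against light in BAT. There, another split called 344 genes against 161, so a structure of the BAT libraries other than the phase stays possible, and what separates the libraries in that split was not tested.

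BMAL1 peaks lay beside rhythmic WAT genes more often than beside others. Expression is a candidate explanation, since genes with a peak had a median log2 level 0.80 above the rest (12.6 against 7.24 CPM) and the odds ratio within bins of expression was 0.842. No biological explanation was tested for this count.

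A hypothesis, tested on part of the regions that prompted it, is that BMAL1 binding may go with opening in the light phase. Over 1 kb from a start site, rhythmic WAT regions with a BMAL1 peak had their own peak from ZT3 to ZT11 in 36.6% of 498 cases, against 25.1% of 2789 without one (odds ratio 1.72, 95% interval 1.40 to 2.12). In BAT the shares were 35.3% of 504 and 17.8% of 5858 (odds ratio 2.53, 95% interval 2.07 to 3.08), although BMAL1 was measured in WAT. The RNA of rhythmic WAT genes went the other way, with a peak in the light for 21.4% of genes with a BMAL1 peak and 36.6% without. That contrast was not taken within bins of expression, although genes with a BMAL1 peak had a higher median level (12.6 against 7.24 CPM). RNA from other cells is also a candidate source of WAT genes higher in the light. The contrast therefore cannot decide whether BMAL1 binding goes with RNA peaks in the light. Among distal regions the share of rhythmic ones did not differ detectably with binding, with odds ratios of 1.06 in WAT (95% interval 0.951 to 1.19) and 1.00 in BAT (0.904 to 1.11), but over all regions it was lower in WAT (odds ratio 0.656, 95% interval 0.600 to 0.717), with 0.941 in BAT (0.877 to 1.01).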
